A study of Macaca mulatta with 52 samples.

How the data were processed

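RNA was measured by sequencing in 52 libraries of rhesus macaque microglia, which the labels place in 13 groups of 4. Per the labels' protocols, total RNA was isolated with the RNeasy kit, and libraries of the cytokine, washout and ex vivo groups were made with the NEBNext Ultra Directional kit, those of the sphere experiment with the NEBNext low-input kit. Kit, animals, age and the sexes of the animals changed together between the sphere experiment and the others. Tests were therefore made within an experiment, except for the ex vivo comparison and for a difference of effects that is named as such. The labels give ages of 2 to 7 for the cytokine animals, 3 to 7 for the washout animals, 11 to 15 for the sphere animals and 7 to 9 for the ex vivo animals, without a unit.

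The authors deposited read counts per gene for each library, as whole numbers for 32386 gene IDs, without a line for unassigned reads. The authors also deposited FPKM tables, fragments scaled to gene length and library size, with gene symbols and positions. Per the submitters' processing notes, Trimmomatic 0.30, TopHat2 2.0.14, SAMtools 1.3 and HTSeq 0.6.1p1 were used, with no role stated for each. The genome build, the annotation, the aligner settings and the strand setting of the counting are not given in the sources used here. Gene models that overlap, antisense pairs and near-identical copies can therefore have exchanged reads. The counts were used for every test. The FPKM tables were used for names and positions only, whose starts were raised by 1, since they list SPP1 at 0 in 41 of 52 libraries where the counts hold it among the most abundant genes. A count table of the whole series was not used here, because its columns repeat the counts per library.

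Symbols were taken from the FPKM tables. A symbol was used for 17416 gene IDs, and 17621 of the gene IDs were found in a reference table of names. For 516 IDs the name differs between the tables of the sphere libraries and the others. The 26 gene lists held 430 names, 16 lists on microglial biology and 10 with markers of other cells. Each library's counts from Y-linked genes matched the sex in its labels in 52 of 52 libraries.

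Counts were compared with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept by filterByExpr with the groups, scaled by the trimmed mean of M-values (TMM), and tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. All libraries of an experiment entered 1 fit without a term for the animal, which can hide differences within animals. The ex vivo group was fitted with the 4 cytokine libraries of M-CSF alone. CPM values use the same scaling. The comparisons were IL-34 against M-CSF without and with TGF-b, TGF-b added to either cytokine and the difference between these additions; each time without serum against serum plus M-CSF, 18 against 4 days, and 22 days without serum against 18 days of washout; and each pair of groups of the sphere experiment. The 11-day effects of the washout and sphere experiments were compared by their difference in 1 fit over both.

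Gene lists were tested with camera at its preset correlation of 0.01, and again with a correlation estimated from the libraries, adjusted over the lists of a comparison. Members were counted over all genes tested and adjusted over the list alone. List levels are means of log2(CPM + 1). For a gene at 0 in a group, the fold was taken against 3 counts per library and is a lower bound that covers counting error only; where a group held 1 to 3 counts, the counts are given. The groups, tests, lists, alternatives and the choice of named genes were fixed before the data were examined. Named genes were 15 anchors of microglial state, called or not; the 6 largest rises and 6 largest falls with a symbol, an adjusted p below 0.05, a mean of at least 10 CPM in the higher group and the same direction in 4 of 4 pairs (ex vivo: no overlap between groups); and up to 4 members of each list with the smallest adjusted p. A few genes that this choice names are not reported here.

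Within an experiment the same replicate number is the same animal, by the labels. Deviations from the group means of libraries of 1 animal had a median correlation of 0.651 (lowest 0.458, 24 pairs) in the cytokine experiment, 0.632 (0.231, 40 pairs) in the washout experiment and 0.401 (0.251, 12 pairs) in the sphere experiment, and every library was closest to its own number (16 of 16, 20 of 20 and 12 of 12). The ex vivo libraries carry replicate numbers of the washout experiment but come from other animals, so they were not paired.

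The scripts were tested on simulated data with the means and library sizes of the real libraries and 200 changed genes. Of 4-fold changes, 84.8 percent were called for IL-34 against M-CSF, 86.2 percent for 18 days of washout, 65.2 percent for spheres against washout and 64.5 percent for ex vivo against culture; of 1.5-fold changes, 9.2, 35.4, 0 and 3.1 percent. In these 4 simulations 7, 3, 3 and 5 unchanged genes were called, and 0 changed genes were called in the wrong direction. With total counts of 12613181 to 78813282 per library, the median SE of a log2 fold change was 0.21 in the cytokine experiment, 0.17 in the washout experiment, 0.34 in the sphere experiment and 0.23 ex vivo.

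Alternatives were DESeq2 1.42.0 with its Wald test, median-of-ratios scaling in edgeR, no filter on low counts, the animal as a replicate block, only the 2 groups compared, and leaving out each library in turn. Added after the data were seen was a sphere experiment fit without animal 9, whose washout library stood apart in interferon genes. So was a cytokine experiment fit with the pericyte and fibroblast list level as a covariate. For each comparison the other splits of the same libraries into groups of the same size were also tested.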

Results

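RNA sequencing was performed on microglia, the resident macrophages of the brain, taken from the subcortical white matter of rhesus macaques. The 52 libraries fell into 13 groups of 4 and came from 16 animals. In a cytokine experiment, cells of 4 animals (2 female, 2 male) were kept for 8 days in serum medium with M-CSF or with IL-34, which are both ligands of the receptor CSF1R, each with or without TGF-b. In a washout experiment, cells of 4 further animals (2 female, 2 male) were kept for 8 days in serum plus M-CSF, or for 4 days in serum followed by 4, 11 or 18 days without serum, or for 22 days without serum from the start. In a sphere experiment, cells of 4 female animals were kept in serum plus M-CSF, in 4 days of serum followed by 11 days without serum, or for the same time together with oligodendrocytes and progenitor or radial glia cells, called spheres here. A final group held RNA of cells of 4 other animals (1 female, 3 male) taken directly after isolation, called ex vivo here. Total counts per library were 21039308 to 78813282 in the cytokine experiment, 18226386 to 20411596 in the washout experiment, 13839521 to 30002301 in the sphere experiment and 12613181 to 33363904 ex vivo.

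Values are CPM, counts scaled to the library total, as mean ± SD over the 4 libraries of a group, or log2 fold changes ± SE between 2 such groups, with p-values from edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment. Values from the model with the animal as a block are marked blocked. Unless a number of pairs is given, every named gene of the cytokine, washout and sphere experiments moved in its direction in 4 of 4 pairs of libraries from the same animal. Gene positions are those of the expression tables, whose genome build is not given in the sources used here. The strand setting of the counting is not given either, so genes that overlap or lie antisense to another gene, and members of families with near-identical copies (MHC class II, matrix metalloproteinase and chemokine genes), carry an uncertainty that the errors leave out.

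Genes were also grouped in 26 lists fixed in advance. For each list the members that rose or fell are counted over all genes tested and, in parentheses, adjusted over the list alone, shortened to alone. The median is that of the members' log2 fold changes. The camera p, from a test with a preset correlation of 0.01 between genes, and the estimated-correlation p, from the same test with the correlation estimated from the libraries, are both adjusted over the lists.

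**Figure D1:**
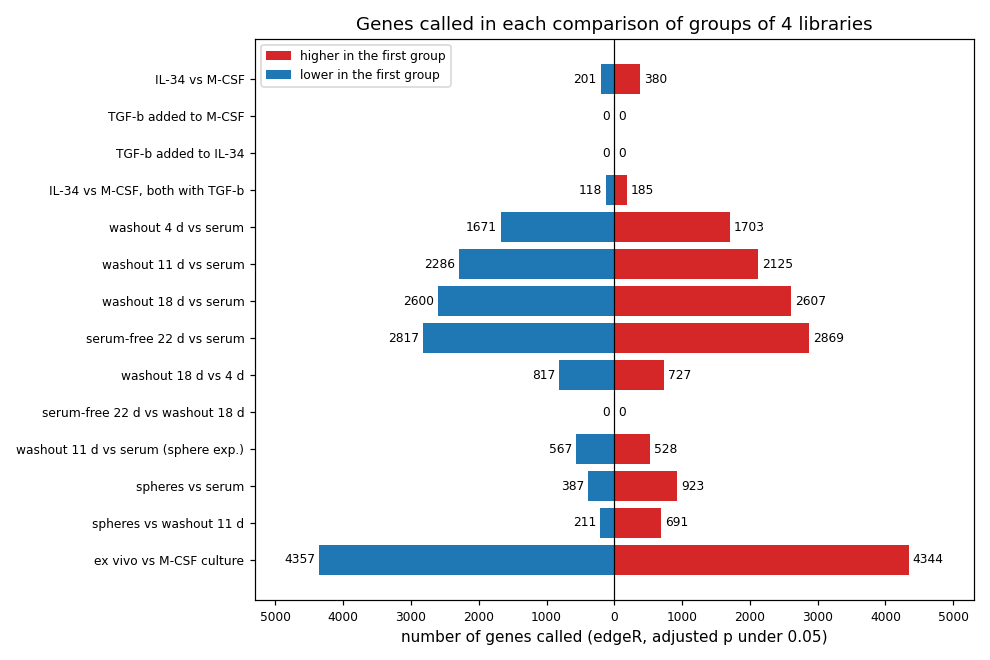
Bars give the number of genes (x axis) with an adjusted p below 0.05 that were higher or lower in each of the comparisons (y axis), with 4 libraries in each group. In both directions together, the numbers ran from 0 for the additions of TGF-b and for 22 against 18 days without serum to 8701 for ex vivo against cultured cells.

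The first comparison asked how microglia differed when IL-34 replaced M-CSF for 8 days in serum medium. Microglia with IL-34 held more mRNA for the fractalkine receptor CX3CR1 (ENSMMUG00000022960, chromosome 2, 103406116 to 103423601), at 145 ± 27.3 against 30 ± 21 CPM (log2 fold change 2.27 ± 0.49, adjusted p = 0.0147). CSF1R, the receptor of both cytokines, rose by 0.53 ± 0.11, adjusted p = 0.0102. CD74, the invariant chain that guides MHC class II assembly (ENSMMUG00000009113, chromosome 6, 148532898 to 148543667), rose by 2.29 ± 0.38, adjusted p = 0.00245, from 406 ± 169 CPM to 1980 ± 522 CPM. The inhibitory Smad gene SMAD6 rose by 2.62 ± 0.31, adjusted p = 0.000279, and the chemokine gene CCL3 fell by 2.14 on the log2 scale (SE 0.34, adjusted p = 0.00203). In all, 380 genes were higher and 201 lower with IL-34 among 13689 tested.

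Among the genes with the largest rises were MASP1, a protease of the lectin pathway of complement (18.3 ± 9.52 against 0.319 ± 0.197 CPM, log2 fold change 5.83 ± 0.60, adjusted p = 8.23e-05), and SOCS2, a suppressor of cytokine signalling (12.9 ± 3.98 against 0.617 ± 0.203 CPM, 4.39 ± 0.36, adjusted p = 2.51e-05). The largest falls included the scavenger receptor gene COLEC12 (-5.84 ± 0.99, adjusted p = 0.00318). P2RY12, a purinergic receptor of resting microglia, did not pass the test (-0.07 ± 0.31, adjusted p = 0.935, 2 of 4 pairs), nor did APOE (0.66 ± 0.32, adjusted p = 0.306, 3 of 4 pairs).

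Of the TGF-beta response list 7 of 16 rose and 1 fell (8 and 1 adjusted over the list alone). Its median was 0.68 (camera p = 2.1e-08, adjusted p = 0.0393 with an estimated correlation). Risers included SMAD6 and CTGF (2.02 ± 0.33). Of the MHC class II list 5 of 15 rose (8 alone, 11 blocked). Its median was 1.64 (camera p = 4.44e-08, estimated-correlation p = 0.129 and 0.00783 blocked). MAMU-DRA rose by 2.50 ± 0.48, adjusted p = 0.007. Of the BMP response list 3 of 8 rose and 1 fell (4 and 1 alone, 6 and 1 blocked). Its median was 0.82 (camera p = 0.000273, estimated-correlation p = 0.0626). ID1 (2.72 ± 0.40), ID3 (2.14 ± 0.41) and SMAD9 (3.35 ± 0.47) rose and BMP2 fell (-3.17 ± 0.66). Of the homeostatic microglia list 3 of 20 rose and 0 fell (3 and 1 alone, 5 and 2 blocked), among them the transcription factor MEF2A (1.27 ± 0.18, adjusted p = 0.000788). Its median was 0.21 (camera adjusted p = 0.0887). The interferon response list had median -0.96, camera p = 3.61e-05, estimated-correlation p = 0.693, while 0 of 24 rose and 0 fell (0 and 0 alone, 0 and 12 blocked). Of the disease-associated microglia list 3 of 19 rose and 2 fell (3 and 3 alone, 3 and 5 blocked). Its median was -0.15 (camera adjusted p = 0.907). The pattern receptor CLEC7A (1.65 ± 0.21) rose. Of the inflammatory list 2 of 18 rose and 2 fell (2 and 3 alone, 5 and 4 blocked).

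Of the pericyte and fibroblast list, markers of other cells, 1 of 8 rose and 1 fell (1 and 1 adjusted over the list alone). Its median was -0.85 (camera adjusted p = 0.285). Of the monocyte and neutrophil list 1 of 5 rose (2 alone, 3 blocked). Its median was 0.80 (camera p = 0.0308, adjusted p = 0.296 with an estimated correlation). Of the extracellular matrix list 1 of 21 rose and 2 fell (1 and 4 alone, 2 and 7 blocked). Its median was -0.38 (camera adjusted p = 0.0876, camera adjusted p = 0.0379 blocked). TGM2, a transglutaminase of that list, rose by 4.13 ± 0.83, adjusted p = 0.0096. The count of 581 genes was 2542 with the animal as a block and 1084 with DESeq2, and fell to 366 without replicate 3 of the IL-34 group and 362 (237 higher) without replicate 4 of the M-CSF group; the 201 lower genes were 105 to 131 without replicate 2, 3 or 4 of IL-34 or replicate 4 of M-CSF.

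The same exchange of cytokines was made in the presence of TGF-b. With IL-34 plus TGF-b against M-CSF plus TGF-b, 185 genes were higher and 118 lower. The rises included SOCS2 (15.5 ± 4.28 against 1.17 ± 0.437 CPM, 3.74 ± 0.34, adjusted p = 9.62e-05) and MCEMP1 (3.77 ± 0.37, adjusted p = 9.62e-05). SMAD6 rose by 2.79 ± 0.31, adjusted p = 0.000225, ID1, a helix-loop-helix target of BMP signalling, by 3.14 ± 0.40, adjusted p = 0.00079, and SMAD9 by 3.40 ± 0.47, adjusted p = 0.00148. ZAP70, a kinase of antigen receptor signalling, was among the falls (1.24 ± 0.708 against 18.4 ± 9.31 CPM, -3.89 ± 0.64, adjusted p = 0.004). Of the 185 higher genes 160 were also higher with IL-34 in the absence of TGF-b, where independent lists of these sizes would share 5.1, and of the 118 lower genes 73 were also lower (1.7 for independent lists); 0 genes were called in opposite directions, and the animals were the same in both comparisons.

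In this comparison fibroblast-made genes fell in part. Of the pericyte and fibroblast list 3 of 8 fell (5 adjusted over the list alone, 5 blocked). Its median was -2.11 (camera p = 6.16e-08, adjusted p = 0.0781 with an estimated correlation). Of the extracellular matrix list 0 of 21 rose and 6 fell (1 and 8 alone, 1 and 9 blocked). Its median was -0.59 (camera p = 7.75e-08, estimated-correlation p = 0.0888). COL6A1 (-2.73 ± 0.52, adjusted p = 0.0105) and COL4A1 (-2.55 ± 0.36, adjusted p = 0.00177), both collagen genes, were among the falls. Of the MHC class II list 2 of 15 rose (5 alone, 10 blocked). Its median was 1.33 (camera p = 1.58e-07, estimated-correlation p = 0.0917 and 0.00787 blocked). CD74 rose from 481 ± 207 CPM to 2070 ± 580 CPM (2.11 ± 0.37, adjusted p = 0.00637). Of the TGF-beta response list 4 of 16 rose and 1 fell (5 and 2 alone). Its median was 0.29 (camera p = 2.21e-05, estimated-correlation p = 0.0888). Of the BMP response list 3 of 8 rose and 1 fell (4 and 1 alone). Its median was 0.55 (camera p = 3.29e-05, estimated-correlation p = 0.0371 and 0.0883 blocked). The count of 303 genes was 1360 with the animal as a block, 627 with DESeq2, 183 with only these 2 groups in the model, 198 without replicate 4 of IL-34 plus TGF-b (the 118 lower genes were 65, 76 and 72 without its replicates 2, 3 and 4) and 91 with the level of the fibroblast list as a covariate, which kept 53 of the calls. Of the genes named for this comparison, SOCS2, MCEMP1, SMAD6, ID1, SMAD9 and ZAP70 were still called with that covariate. With it COL6A1 was at -0.63 ± 0.41 (adjusted p = 0.502) and COL4A1 at -1.38 ± 0.36 (adjusted p = 0.0958), and CD74 at 2.63 ± 0.58 (adjusted p = 0.0563), a larger fold with a larger SE.

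The addition of TGF-b itself was examined on either cytokine. On M-CSF P2RY12 (ENSMMUG00000001105, chromosome 2, 138118783 to 138165594) stood at 90.8 ± 28.2 against 50.7 ± 17.5 CPM (log2 fold change 0.84 ± 0.31, adjusted p = 0.713 and 0.011 blocked). GPR34, a lysophosphatidylserine receptor, stood at 196 ± 59.2 against 108 ± 22.8 CPM (0.86 ± 0.23, adjusted p = 0.683 and 0.00418 blocked). Both rose in 4 of 4 animals, and passed the test blocked but not unblocked. On IL-34 the proliferation marker MKI67 stood at 537 ± 223 against 300 ± 53.5 CPM (0.84 ± 0.32, adjusted p = 1, 3 of 4 pairs), and on M-CSF at 540 ± 178 against 315 ± 69.3 CPM (0.78 ± 0.32, adjusted p = 0.713, 3 of 4 pairs). edgeR's quasi-likelihood test called 0 genes on M-CSF (924 at an unadjusted p below 0.05, 2589 blocked and 516 to 1576 without single libraries; 11 with DESeq2; 27 with the animal as a block; 2 without replicate 2 of the M-CSF group) and 0 on IL-34 (417 at an unadjusted p below 0.05, 1384 blocked and 830 without replicate 1 of IL-34 plus TGF-b; 10 with DESeq2; 9 with the animal as a block).

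With camera, lists were called as wholes although no member passed over all genes. On M-CSF, the homeostatic microglia list had median 0.28, camera p = 0.000927, adjusted p = 0.42 with an estimated correlation; 0 of 20 rose and 0 fell (1 and 0 adjusted over the list alone, 2 and 0 blocked). The interferon response list had median -0.67, camera p = 1.67e-05, estimated-correlation p = 0.699, the cell cycle list median 0.46, camera p = 1.67e-05, estimated-correlation p = 0.699, and the TGF-beta response list median 0.38, camera p = 0.0195, estimated-correlation p = 0.42, where 0 of 16 rose and 0 fell (1 and 0 alone). The pericyte and fibroblast list moved with them (median 0.71, camera p = 0.00439, estimated-correlation p = 0.42). On IL-34 the cell cycle list had median 0.63, camera p = 6.36e-20, estimated-correlation p = 0.785, and the interferon response list median 0.39, camera p = 0.00486, estimated-correlation p = 0.835. In replicate 1 the cell cycle level, as mean log2(CPM + 1), was 5.86 with IL-34 plus TGF-b and 5.90 with IL-34, and 6.08 with M-CSF plus TGF-b and 6.31 with M-CSF; the other libraries with TGF-b stood at 7.12 to 7.21 and 7.09 to 7.34. The matrix list (median -0.39, camera p = 0.0097, estimated-correlation p = 0.785) and the pericyte and fibroblast list (median -0.56, camera p = 0.00842, estimated-correlation p = 0.785) were lower. The test of the difference between the TGF-b effects on the 2 cytokines called 0 genes with edgeR's quasi-likelihood test, with 203 at an unadjusted p below 0.05 (803 blocked, 158 to 504 without single libraries), 0 with DESeq2 and 1 without replicate 1 of the IL-34 group. In simulated counts with the spread of this experiment, 84.6 percent of 4-fold and 43.3 percent of 2-fold changes were called for the addition to M-CSF.

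**Figure D2:**
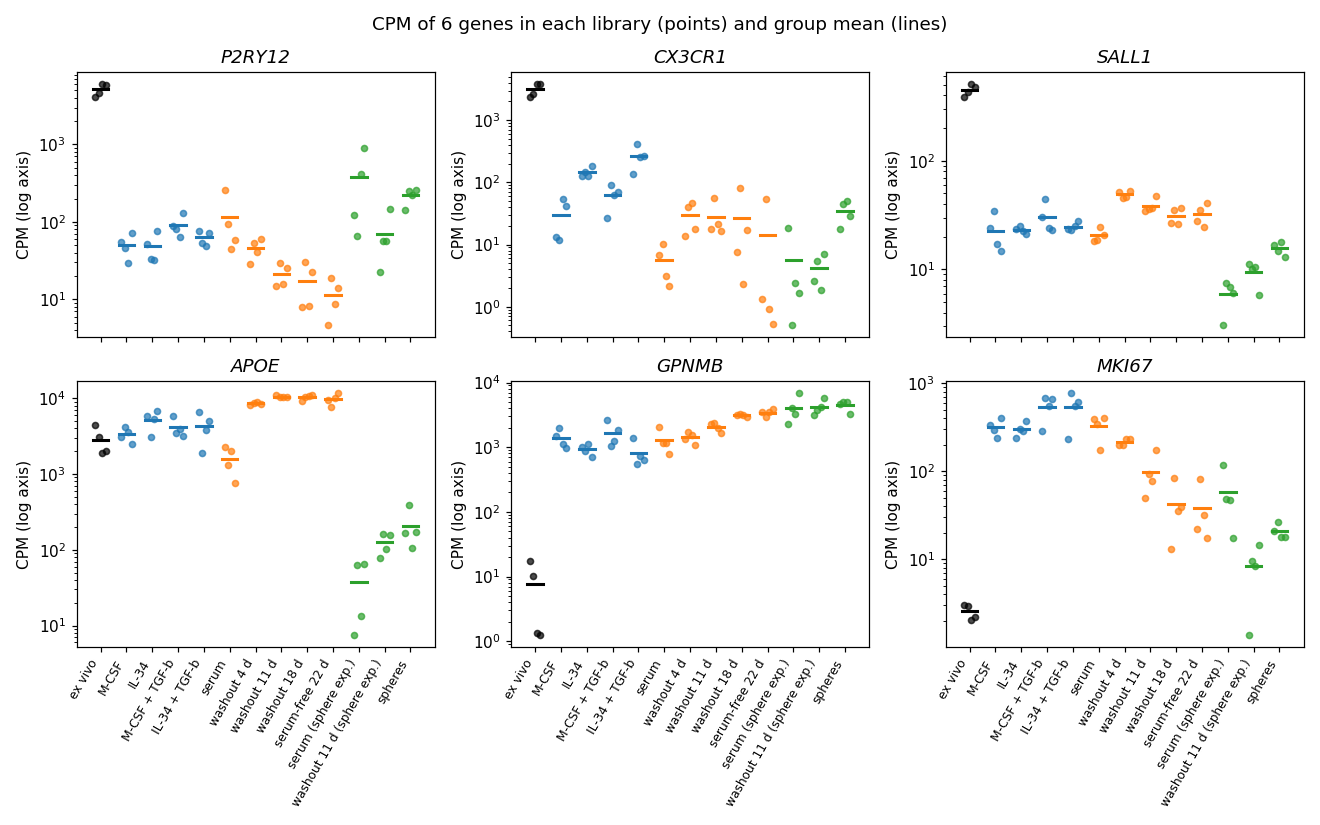
Points give the CPM of P2RY12, CX3CR1, SALL1, APOE, GPNMB and MKI67 in each library (y axis, log scale) by group (x axis), and lines the mean of the 4 libraries of a group. P2RY12 averaged 5170 CPM ex vivo and 114 CPM in the serum group of the washout experiment.

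The washout experiment asked what happened when serum was withdrawn from microglia that had been kept in serum plus M-CSF. The cholesterol exporter gene ABCG1 (ENSMMUG00000018058, chromosome 3, 4397927 to 4491646) rose from 0.724 ± 0.97 CPM in serum to 49.4 ± 30.4 CPM after 4 days and 208 ± 88.2 CPM after 18 days without serum (log2 fold changes 6.04 ± 0.76, adjusted p = 3.36e-05, and 8.12 ± 0.80, adjusted p = 1.71e-06). APOE, the main apolipoprotein of brain lipid transport (ENSMMUG00000014305, chromosome 19, 40213748 to 40218119), rose from 1590 ± 677 CPM to 8530 ± 406 CPM at 4 days (2.43 ± 0.23, adjusted p = 3.16e-06). It stood at 10300 ± 847 CPM at 18 days (2.70 ± 0.24, adjusted p = 7.02e-07). LYVE1, a hyaluronan receptor of border macrophages, fell from 24.9 ± 34.4 CPM to 0.245 ± 0.456 CPM at 4 days (-6.65 ± 1.42, adjusted p = 0.00266). Against the serum group, 1703 genes were higher and 1671 lower at 4 days, 2125 and 2286 at 11 days, 2607 and 2600 at 18 days, and 2869 and 2817 at 22 days without serum, among 13699 tested; at 4 days the total of 3374 was 5421 with the animal as a block. With only the 2 groups in the model, 1095 genes were lower at 4 days and 1672 higher at 18 days.

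At 4 days the largest rises also included the chemokine CCL22 (6.37 ± 0.92, adjusted p = 0.000105). The falls included the growth factor gene IGF1 (-5.36 ± 1.21, adjusted p = 0.0039) and the folate receptor gene FOLR2 (-4.22 ± 0.54, adjusted p = 4.02e-05). By 18 days MME, the membrane peptidase neprilysin (5.86 ± 0.86, adjusted p = 6.28e-05) and the smooth muscle actin gene ACTG2 (7.43 ± 1.68, adjusted p = 0.00215) were among the largest rises. ZAP70 (-5.88 ± 0.65, adjusted p = 4.54e-06) and the interferon-induced gene IFI27 (-5.58 ± 1.19, adjusted p = 0.00138) were among the largest falls.

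The genes of cholesterol synthesis rose early and then fell. Of the 23 cholesterol synthesis genes, 20, 0, 0 and 1 rose and 0, 9, 14 and 13 fell at 4, 11, 18 and 22 days without serum (22, 0, 0 and 1, and 0, 10, 16 and 14, adjusted over the list alone). Medians were 0.92, -0.34, -0.62 and -0.60, with camera p = 4.82e-05, adjusted p = 0.409 with an estimated correlation at 18 days. DHCR7, a late enzyme of the pathway, rose at 4 days (1.82 ± 0.28, adjusted p = 0.000199). At 18 days SQLE, squalene epoxidase, had fallen (24.8 ± 3.38 against 81.2 ± 26.2 CPM, -1.71 ± 0.20, adjusted p = 6.26e-06), as had FDPS (-1.49 ± 0.24) and INSIG1, a sterol-dependent brake on the pathway (-2.16 ± 0.33).

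Targets of LXR, the nuclear receptors that sense oxysterols, were higher at each time. Of the 11 LXR targets, 9, 8, 8 and 9 rose and 1, 1, 1 and 1 fell at 4, 11, 18 and 22 days without serum (10, 8, 9 and 9, and 1, 1, 1 and 1, adjusted over the list alone). Medians were 1.56, 1.26, 1.28 and 1.32, with camera p = 2.25e-06, adjusted p = 0.23 with an estimated correlation at 18 days. At 18 days the exporter ABCA1 (3.06 ± 0.48, adjusted p = 0.000122) had risen with ABCG1.

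Proliferation genes fell. Of the 30 cell cycle genes, 0 each rose and 0, 29, 30 and 30 fell at 4, 11, 18 and 22 days without serum (0 each, and 0, 29, 30 and 30, adjusted over the list alone). With the animal as a block, 0 rose and 4 fell at 4 days. Medians were -0.44, -1.53, -2.42 and -2.50, with camera p = 2.74e-20, adjusted p = 0.23 with an estimated correlation at 18 days. MKI67 (ENSMMUG00000044121, chromosome 9, 124210012 to 124238734) fell from 326 ± 104 CPM to 42.7 ± 29.3 CPM at 18 days (-2.93 ± 0.54, adjusted p = 0.000444) and cyclin B1, CCNB1, from 71.9 ± 28.4 CPM to 7.49 ± 3.53 CPM (-3.26 ± 0.46, adjusted p = 3.92e-05).

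Interferon response genes fell as well. Of the 24 interferon response genes, 0, 0, 1 and 1 rose and 9, 17, 19 and 20 fell at 4, 11, 18 and 22 days without serum (0, 1, 1 and 1, and 9, 18, 19 and 20, adjusted over the list alone). Medians were -0.73, -1.23, -1.81 and -2.05, with camera p = 7.89e-14, adjusted p = 0.23 with an estimated correlation at 18 days. The antiviral genes MX2 (-2.88 ± 0.30, adjusted p = 2.84e-06) and OAS2 (-2.58 ± 0.29, adjusted p = 5.54e-06) were among the falls at 18 days.

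Antigen presentation genes rose. Of the 14 MHC class II genes, 4, 9, 11 and 10 rose and 0 each fell at 4, 11, 18 and 22 days without serum (4, 10, 12 and 10, and 0 each, adjusted over the list alone). With the animal as a block, 6 rose and 2 fell at 4 days. Medians were 0.73, 1.5, 2.06 and 1.25, with camera p = 1.37e-05, adjusted p = 0.23 with an estimated correlation at 18 days. CD74 rose from 130 ± 102 CPM to 1840 ± 1300 CPM (3.82 ± 0.73, adjusted p = 0.000556) and MAMU-DRA from 50.8 ± 32.3 CPM to 1010 ± 608 CPM (4.31 ± 0.62, adjusted p = 5.19e-05) at 18 days.

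Genes of border and tissue macrophages fell in part. Of the 15 border macrophage genes, 0 each rose and 8, 7, 5 and 9 fell at 4, 11, 18 and 22 days without serum (0 each, and 8, 7, 5 and 11, adjusted over the list alone). With the animal as a block, 0 rose and 10 fell at 18 days. Medians were -1.58, -1.23, -1.04 and -1.43, with camera p = 0.00804, adjusted p = 0.279 with an estimated correlation at 18 days. The mannose receptor gene MRC1 (ENSMMUG00000011620, chromosome 9, 17960328 to 18059636) fell from 1060 ± 196 CPM to 514 ± 55.3 CPM at 18 days (-1.04 ± 0.14, adjusted p = 1.96e-05).

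The homeostatic microglia list went both ways. Of the 20 homeostatic genes, 3, 4, 5 and 5 rose and 6, 7, 7 and 8 fell at 4, 11, 18 and 22 days without serum (3, 4, 5 and 5, and 6, 7, 7 and 8, adjusted over the list alone). Medians were -0.30, -0.13, -0.01 and -0.27, with camera adjusted p = 0.776 at 18 days. SALL1, a transcription factor of microglia (ENSMMUG00000017200, chromosome 20, 35069003 to 35085410), rose at 4 days (49 ± 3.79 against 20.6 ± 2.94 CPM, 1.25 ± 0.16, adjusted p = 3.73e-05) and was higher at 18 days (0.60 ± 0.16, adjusted p = 0.00606). P2RY12 fell from 114 ± 99.3 CPM to 17.3 ± 11 CPM at 18 days (-2.73 ± 0.57, adjusted p = 0.00125), with the checkpoint gene VSIR (-1.86 ± 0.21) and BIN1 (-1.38 ± 0.28). CX3CR1 did not pass the test (2.27 ± 1.21, adjusted p = 0.151, 3 of 4 pairs).

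Of the 19 disease-associated microglia genes, 6, 7, 7 and 9 rose and 3, 2, 2 and 2 fell at 4, 11, 18 and 22 days without serum (6, 7, 8 and 10, and 3, 2, 2 and 3, adjusted over the list alone). Medians were 0.13, 0.30, 0.41 and 0.48, with camera p = 0.000602, adjusted p = 0.257 with an estimated correlation at 18 days. At 18 days the lysosomal glycoprotein gene GPNMB stood at 3110 ± 119 against 1300 ± 541 CPM (1.26 ± 0.22, adjusted p = 0.00024), APOC1 at 272 ± 48.4 against 11.9 ± 8.23 CPM (4.52 ± 0.43, adjusted p = 1.33e-06) and CLEC7A at 113 ± 5.61 against 44.3 ± 7.94 CPM (1.36 ± 0.12, adjusted p = 6.53e-07).

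The other lists at 18 days were as follows. Of the BMP response list 6 of 9 rose (6 adjusted over the list alone). Its median was 1.65 (camera p = 0.0022, adjusted p = 0.23 with an estimated correlation). ID3 rose by 2.84 ± 0.45, adjusted p = 0.000126. Of the TGF-beta response list 10 of 16 rose and 2 fell (10 and 2 alone). Its median was 0.64 (camera p = 0.0139, estimated-correlation p = 0.34). SMAD6 (2.05 ± 0.33) rose and TGFBI (-3.02 ± 0.42) and SMAD3 (-3.09 ± 0.41) fell. Of the immediate early list 9 of 18 rose and 0 fell (11 and 1 alone). Its median was 0.52 (camera p = 0.00604, estimated-correlation p = 0.257). Of the inflammatory list 6 of 17 rose and 1 fell (6 and 1 alone). Its median was 0.27 (camera adjusted p = 0.297). Of the glycolysis list 2 of 17 rose and 10 fell (2 and 10 alone). Its median was -0.49 (camera p = 0.000383, estimated-correlation p = 0.257). Of the complement list 4 of 16 rose and 3 fell (4 and 3 alone). Its median was -0.18 (camera adjusted p = 0.902, the test pointing up). C3 (2.41 ± 0.31) and CFD (4.98 ± 0.65) rose. Of the lysosome list 5 of 23 rose and 4 fell (6 and 4 alone, 9 and 6 blocked). Its median was 0.00 (camera adjusted p = 0.683, the test pointing up). Of the matrix list 5 of 21 rose and 2 fell (4 and 2 alone, 8 and 4 blocked). Its median was 0.34 (camera adjusted p = 0.38).

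Markers of other cells were measured beside these lists. At 4 days, of the T and NK cell list 2 of 5 fell (2 adjusted over the list alone). Its median was -0.35 (camera adjusted p = 0.168). Of the progenitor list 1 of 7 rose (1 alone, 5 blocked). Its median was 1.48 (camera p = 0.0185, adjusted p = 0.0943 with an estimated correlation). At 18 days, of the T and NK cell list 0 of 5 rose and 1 fell (0 and 1 alone, 1 and 2 blocked). Its median was -0.01 (camera adjusted p = 0.503). Of the monocyte and neutrophil list 1 of 4 rose and 2 fell (1 and 2 alone). Its median was -0.07 (camera adjusted p = 0.776). Of the pericyte and fibroblast list 1 of 7 rose and 0 fell (1 and 0 alone, 1 and 3 blocked). Its median was -1.31 (camera adjusted p = 0.683). Of the neuron list 3 of 6 rose (3 alone). Its median was 1.06 (camera adjusted p = 0.275).

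Within the washout, 18 days were compared with 4 days, so time in culture differed again. Of the cholesterol synthesis list 22 of 23 fell (22 adjusted over the list alone). Its median was -1.75 (camera p = 1.2e-64, adjusted p = 0.00288 with an estimated correlation). SQLE (-2.36 ± 0.20, adjusted p = 2.84e-06), CYP51A1 (-2.32 ± 0.22) and HMGCS1 (-1.80 ± 0.15) fell. FOLR2 rose again, from 4.77 ± 3.07 CPM to 47.3 ± 24.3 CPM (3.31 ± 0.52, adjusted p = 0.000966), with GPNMB (1.14 ± 0.21, adjusted p = 0.00291). Of the cell cycle list 27 of 30 fell (29 alone). Its median was -2.02 (camera p = 6.6e-33, estimated-correlation p = 0.158). Of the interferon list 13 of 24 fell (18 alone). Its median was -1.13 (camera p = 5.87e-14, estimated-correlation p = 0.189). Of the MHC class II list 6 of 14 rose (11 alone, 11 blocked). Its median was 1.45 (camera p = 1.65e-06, estimated-correlation p = 0.206). Of the astrocyte list 1 of 13 fell (1 alone, 6 blocked). Its median was -0.86 (camera p = 0.0451, estimated-correlation p = 0.749). In all 727 genes were higher and 817 lower at 18 days; the total of 1544 was 3390 with the animal as a block and 974 (444 higher, 530 lower) without replicate 8 of the 18-day group, and the 727 higher genes were 479 without the low-count filter and 454, 394 and 416 without replicates 5, 6 and 7 of the 4-day group.

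Cells without serum for 22 days were compared with the 18-day washout. APOE stood at 9680 ± 1580 against 10300 ± 847 CPM (-0.09 ± 0.22, adjusted p = 1, 2 of 4 pairs), MKI67 at 37.8 ± 29.1 against 42.7 ± 29.3 CPM (-0.17 ± 0.51, adjusted p = 1, 3 of 4 pairs) and P2RY12 at 11.5 ± 6.16 against 17.3 ± 11 CPM (-0.58 ± 0.55, adjusted p = 1, 3 of 4 pairs). edgeR's quasi-likelihood test called 0 genes, as did DESeq2 and the model with the animal as a block, with 261 genes at an unadjusted p below 0.05 (1126 blocked, 961 without replicate 7 of the 18-day group, 611 without replicate 6 of the 22-day group and 414 without the low-count filter). Of the tested genes, 77.6 percent had a 95 percent interval within a 2-fold change. The MHC class II list had median -0.65, camera p = 1.24e-05, adjusted p = 0.24 with an estimated correlation, the border macrophage list median -0.60, camera p = 0.000373, estimated-correlation p = 0.24 and the homeostatic list median -0.24, camera p = 0.00123, estimated-correlation p = 0.295.

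**Figure D3:**
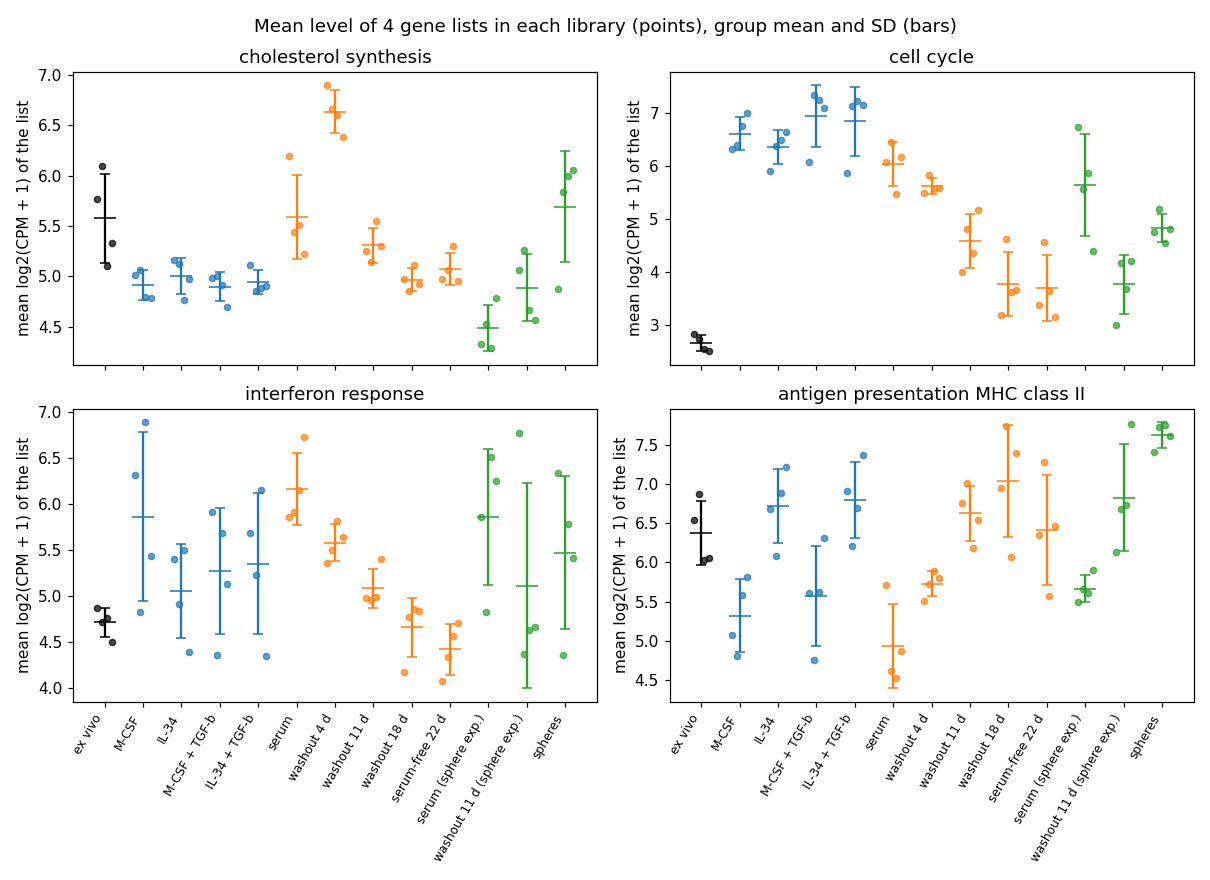
Points give the mean log2(CPM + 1) over the genes of the cholesterol synthesis, cell cycle, interferon response and MHC class II lists tested in that experiment in each library (y axis) by group (x axis), with bars for the mean and SD of the 4 libraries of a group. In the washout experiment 20 of 23 cholesterol synthesis genes rose at 4 days and 14 fell at 18 days, when 30 of 30 cell cycle genes had fallen.

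The sphere experiment held its own serum and washout groups, from 4 other animals and with a low-input library kit. After 11 days of washout ABCG1 rose from 0.873 ± 1.25 CPM to 121 ± 28.4 CPM (7.07 ± 0.96, adjusted p = 0.0014), the protease gene MMP7 from 1.31 ± 0.926 CPM to 187 ± 132 CPM (7.18 ± 0.89, adjusted p = 0.000912) and CCL22 by 6.54 ± 1.01, adjusted p = 0.00285. TGFBI, a TGF-b-induced matrix protein, fell from 287 ± 351 CPM to 5.5 ± 1.05 CPM (-5.70 ± 0.86, adjusted p = 0.0025), with ZAP70 (-5.74 ± 0.65, adjusted p = 0.000585). APOE stood at 126 ± 42.4 against 37 ± 30.7 CPM (1.76 ± 0.62, adjusted p = 0.104 and 0.00765 blocked) and P2RY12 at 70.7 ± 54 against 377 ± 382 CPM (-2.42 ± 0.73, adjusted p = 0.0606 and 0.0136 blocked). In all 528 genes were higher and 567 lower among 13112 tested.

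Of the cell cycle list 23 of 30 fell (28 adjusted over the list alone). Its median was -2.39 (camera p = 8.21e-23, adjusted p = 0.198 with an estimated correlation). Of the border macrophage list 9 of 14 fell (14 alone). Its median was -2.07 (camera p = 8.89e-12, estimated-correlation p = 0.00306). The scavenger receptor CD36 (-2.52 ± 0.38) and LYVE1 (-6.85 ± 1.47) fell. Of the MHC class II list 5 of 14 rose (8 alone). Its median was 0.98 (camera p = 0.000279, estimated-correlation p = 0.198). CD74 (2.98 ± 0.57, adjusted p = 0.00813) and MAMU-DRA (2.44 ± 0.52) rose. Of the LXR list 3 of 11 rose and 1 fell (6 and 1 alone, 6 and 1 blocked). Its median was 0.97 (camera p = 0.000155, estimated-correlation p = 0.198). Of the homeostatic list 0 of 20 rose and 5 fell (1 and 8 alone, 1 and 8 blocked). Its median was -0.58 (camera p = 0.00448, estimated-correlation p = 0.198). VSIR (-2.05 ± 0.31) fell. Of the complement list 2 of 16 rose and 6 fell (2 and 7 alone). Its median was -0.52 (camera p = 0.00385, estimated-correlation p = 0.123). C3 rose (1.75 ± 0.30). Markers of other cells were also lower in part. Of the pericyte and fibroblast list 0 of 8 rose and 0 fell (1 and 1 alone, 1 and 6 blocked). Its median was -2.77 (camera p = 0.0202, estimated-correlation p = 0.498). Of the T and NK cell list 2 of 7 fell (2 alone). Its median was -0.60 (camera adjusted p = 0.182), and -0.04 with the gene at 0 counts at its bound. Of the astrocyte list 3 of 13 fell (3 alone, 5 blocked). Its median was -0.81 (camera adjusted p = 0.118). Of the monocyte and neutrophil list 0 of 5 rose and 2 fell (0 and 2 alone). Its median was -0.27 (camera adjusted p = 0.206). The count of 1095 genes was 1726 with the animal as a block, 1806 with DESeq2 and 612 with only these 2 groups. It was 699 (335 lower) without replicate 10 and 654 (348 higher, 306 lower) without replicate 11 of the washout group. Without animal 9, whose washout library stood apart in interferon genes, it was 457, with 406 calls kept. Of genes tested in both experiments, 389 were higher after 11 days of washout in both (80.5 for independent lists) and 377 lower in both (93.2), with 0 called in opposite directions and no shared libraries.

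The test of the difference between the 11-day washout effects of the 2 experiments called 0 genes with edgeR's quasi-likelihood test, with 725 genes at an unadjusted p below 0.05 (1244 blocked), 45 with DESeq2, and 2 without either replicate 11 or replicate 12 of the sphere experiment's washout group. The median SE of these differences was 0.43 on the log2 scale, against 0.17 in the washout experiment. In simulated counts 37.9 percent of 4-fold differences were called, so smaller ones were mostly not detectable here.

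Spheres were compared with serum plus M-CSF (shorter in culture) and with the 11-day washout. The myelin protein gene MOG stood at 161 ± 93.3 against 0.107 ± 0.0759 CPM in spheres and serum (10.48 ± 0.80, adjusted p = 1.07e-05) and the astrocyte filament gene GFAP at 2120 ± 483 against 60.4 ± 47.4 CPM (5.13 ± 0.63, adjusted p = 0.000257). Of the oligodendrocyte list 14 of 14 rose (14 adjusted over the list alone). Its median was 9.71 (camera p = 1.85e-55, adjusted p = 0.00494 with an estimated correlation). Of the astrocyte and radial glia list 9 of 13 rose (9 alone). Its median was 4.14 (camera p = 3.11e-14, estimated-correlation p = 0.00194). Of the oligodendrocyte progenitor list 3 of 6 rose (4 alone), of the neuron list 4 of 5 rose (4 alone) and of the T and NK cell list 3 of 7 rose and 0 fell (3 and 1 alone). Among the largest rises OPALIN, an oligodendrocyte membrane protein, stood at 182 ± 115 CPM in spheres and at 3 counts over the 4 serum libraries, MAL, a myelin proteolipid, at 52 ± 26.4 CPM and 1 count. FA2H, which makes the hydroxylated fatty acids of myelin, was at least 64-fold higher, against 3 counts per library as the floor of genes at 0 counts.

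Beside these, genes of the microglial lists differed between spheres and serum. CD74 stood at 4260 ± 1480 against 246 ± 120 CPM (4.11 ± 0.60, adjusted p = 0.000805) and SALL1 at 15.7 ± 2.1 against 5.91 ± 1.99 CPM (1.40 ± 0.30, adjusted p = 0.00946). MRC1 fell (-1.70 ± 0.29, adjusted p = 0.00217). Of the cholesterol synthesis list 12 of 23 rose and 0 fell (17 and 0 adjusted over the list alone). Its median was 1.34 (camera p = 7.67e-10, adjusted p = 0.181 with an estimated correlation). HMGCS1 rose (2.15 ± 0.26), a gene that oligodendrocytes also use. Of the MHC class II list 6 of 14 rose and 1 fell (9 and 2 alone). Its median was 1.85 (camera p = 9.47e-06, estimated-correlation p = 0.109). Of the border macrophage list 8 of 14 fell (8 alone). Its median was -1.49 (camera p = 9.93e-07, estimated-correlation p = 0.00607). The pericyte and fibroblast list had median -1.42, camera p = 0.0452, estimated-correlation p = 0.533 (camera adjusted p = 0.0506 with median-of-ratios scaling). In all 923 genes were higher and 387 lower; the total of 1310 was 2018 with the animal as a block and 2146 with DESeq2. The 387 lower genes were 232, 232 and 225 without sphere replicates 10, 11 and 12, 634 without serum replicate 12 and 250 without animal 9. SPP1, osteopontin, took 16.9 ± 1.95 percent of all counts in serum and 10.1 ± 2.91 percent in spheres.

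Against the 11-day washout, spheres held more BIN1, a membrane-bending adaptor of the homeostatic list that oligodendrocytes also express (73.7 ± 15.5 against 18.3 ± 6.38 CPM, 2.01 ± 0.30, adjusted p = 0.00103). LCN2, the iron-binding lipocalin, fell (-4.63 ± 0.62, adjusted p = 0.000472), as did ABCG1 (9.29 ± 3.34 against 121 ± 28.4 CPM, -3.70 ± 0.80, adjusted p = 0.012). Of the homeostatic list 2 of 20 rose (4 adjusted over the list alone, 6 blocked). Its median was 0.73 (camera p = 0.000619, adjusted p = 0.221 and 0.0278 blocked with an estimated correlation). P2RY12 stood at 220 ± 55.1 against 70.7 ± 54 CPM (1.64 ± 0.71, adjusted p = 0.243 and 0.0214 blocked), GPR34 had a log2 fold change of 1.13 ± 0.35, adjusted p = 0.0738 and 0.0325 blocked, and CX3CR1 of 3.06 ± 0.88, adjusted p = 0.0552. Of the cholesterol synthesis list 5 of 23 rose (10 alone). Its median was 0.71 (camera p = 5.17e-06, estimated-correlation p = 0.458). SQLE (1.64 ± 0.30) and CYP51A1 (1.68 ± 0.32) rose. Of the LXR list 2 of 11 fell (4 alone, 4 blocked). Its median was -0.67 (camera p = 0.00577, estimated-correlation p = 0.462). In the cell cycle list 0 of 30 rose and 0 fell (0 and 0 alone). Its median was 1.13 (camera p = 4.97e-06, estimated-correlation p = 0.585).

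Markers of other cells moved beside these. Of the oligodendrocyte list 14 of 14 rose (14 adjusted over the list alone). Its median was 10.48 (camera p = 3.65e-69, adjusted p = 0.00213 with an estimated correlation), and 10.16 with the gene at 0 counts set at its bound. Of the astrocyte list 9 of 13 rose (11 alone). Its median was 3.81 (camera p = 3.32e-20, estimated-correlation p = 0.000343). Of the T and NK cell list 2 of 7 rose (4 alone, 4 blocked). Its median was 2.14 (camera p = 0.00577, estimated-correlation p = 0.11). NKG7, a cytotoxic granule gene, was at least 23.4-fold higher. The largest rises included OPALIN (at least 1130-fold higher), which stood at 0 counts in the washout group. In all 691 genes were higher and 211 lower, and the total of 902 was 1677 with DESeq2. The 211 lower genes were 440 with DESeq2, 369 blocked, 335 with only these 2 groups in the model, 89 without sphere replicate 10, 128 to 139 without any other single library except washout replicate 12, and 88 without animal 9.

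**Figure D4:**
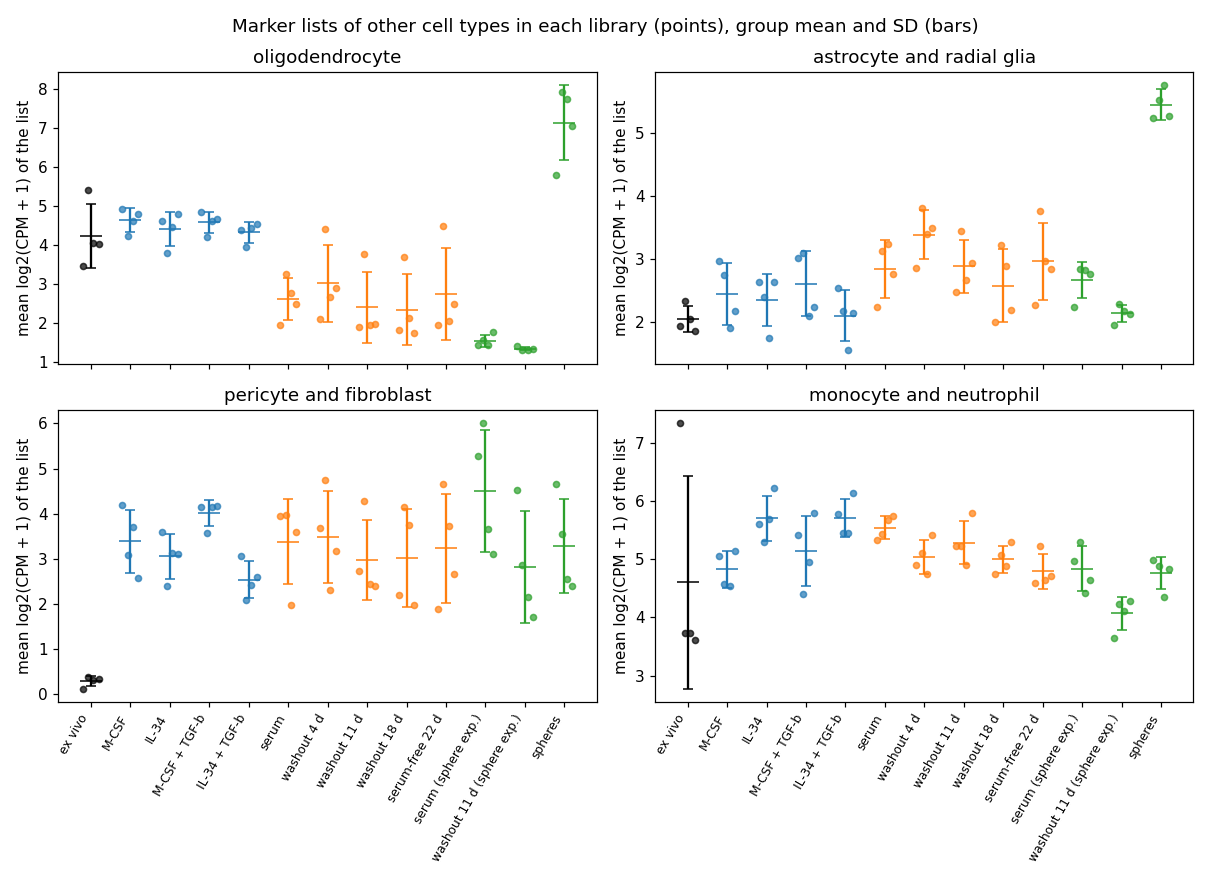
Points give the mean log2(CPM + 1) over the marker genes of oligodendrocytes, astrocytes and radial glia, pericytes and fibroblasts, and monocytes and neutrophils tested in that experiment (oligodendrocytes: 4 in the cytokine experiment, 7 ex vivo, 14 in the others) in each library (y axis) by group (x axis), with bars for the mean and SD of the 4 libraries of a group. Within the sphere experiment the oligodendrocyte level was highest in spheres, where 14 of 14 of these genes were above their level in the serum group.

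The ex vivo group was compared with microglia cultured for 8 days in serum plus M-CSF, to see what culture changed. Freshly isolated cells held P2RY12 at 5170 ± 975 against 52.5 ± 18.9 CPM (6.62 ± 0.34, adjusted p = 7.73e-07) and P2RY13, a related receptor (ENSMMUG00000038998, chromosome 2, 138108387 to 138113421), at 1040 ± 146 against 0.908 ± 0.704 CPM (10.11 ± 0.55, adjusted p = 1.02e-06). TMEM119, a marker of parenchymal microglia (ENSMMUG00000006821, chromosome 11, 108497064 to 108506008), rose by 7.92 ± 0.77, adjusted p = 1.76e-05, CX3CR1 by 6.66 ± 0.60, adjusted p = 1.17e-05, SALL1 by 4.26 ± 0.27, adjusted p = 1.89e-06, CSF1R by 2.18 ± 0.17, adjusted p = 4.32e-06 and TREM2 by 1.51 ± 0.12, adjusted p = 5.25e-06. Lower ex vivo were GPNMB (7.61 ± 7.86 against 1440 ± 445 CPM, -7.55 ± 0.91, adjusted p = 6.77e-05), SPP1 (-5.34 ± 0.51, adjusted p = 1.6e-05) and MKI67 (2.55 ± 0.508 against 327 ± 76.6 CPM, -6.99 ± 0.25, adjusted p = 3.56e-07). APOE (-0.27 ± 0.29, adjusted p = 0.421) and MRC1 (-0.53 ± 0.23, adjusted p = 0.0643) did not pass the test. In all 4344 genes were higher and 4357 lower among 13520 tested.

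Among the largest rises ex vivo HBB, the beta chain of hemoglobin, stood at 59.8 ± 36.5 CPM ex vivo and 0 counts in culture (at least 516-fold higher), the neutrophil gene S100A9 at 104 ± 203 CPM (409 in replicate 5, 2.16 to 3.01 in the others) and 1 count, and the synaptic gene SNAP25 at 54.6 ± 28.1 CPM and 1 count. Among the falls the macrophage elastase gene MMP12 stood at 315 ± 285 CPM in culture and was at least 1860-fold lower ex vivo, and the collagen gene COL1A2 at least 521-fold lower. Culture values in this comparison are scaled with the ex vivo libraries.

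Of the homeostatic list 15 of 20 rose and 1 fell (15 and 1 adjusted over the list alone). Its median was 1.88 (camera p = 9.26e-09, adjusted p = 0.222 with an estimated correlation). Of the disease-associated list 2 of 19 rose and 15 fell (2 and 15 alone). Its median was -2.64 (camera p = 7.27e-07, estimated-correlation p = 0.222). The lysosomal proteases CTSL (-4.39 ± 0.21) and CTSD (-3.56 ± 0.21) fell. Of the cell cycle list 30 of 30 fell (30 alone). Its median was -4.51 (camera p = 9.31e-28, estimated-correlation p = 0.222). Of the immediate early and heat shock list 17 of 19 rose and 1 fell (17 and 1 alone). Its median was 2.62 (camera p = 7.27e-07, estimated-correlation p = 0.415). FOSB (8.91 ± 0.54) and the chaperone gene DNAJB1 (4.70 ± 0.33) rose. Of the lysosome list 3 of 23 rose and 18 fell (3 and 18 alone). Its median was -1.06 (camera p = 0.000482, estimated-correlation p = 0.279). Of the glycolysis list 1 of 18 rose and 13 fell (1 and 13 alone). Its median was -1.99 (camera p = 1.45e-07, estimated-correlation p = 0.222). Of the matrix list 17 of 20 fell (17 alone). Its median was -4.47 (camera p = 6.75e-05, estimated-correlation p = 0.222).

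The remaining microglial lists had no call as a whole. Of the interferon list 1 of 24 rose and 14 fell (1 and 14 adjusted over the list alone). Its median was -1.48 (camera adjusted p = 0.0788). Of the MHC class II list 8 of 15 rose and 1 fell (8 and 1 alone). Its median was 0.97 (camera adjusted p = 0.264). Of the complement list 6 of 16 rose and 7 fell (6 and 8 alone). Its median was -0.40 (camera adjusted p = 0.31, the test pointing up). C3 (4.78 ± 0.34) and CFD (6.55 ± 0.25) rose. Of the TGF-beta list 9 of 16 rose and 2 fell (9 and 2 alone). Its median was 1.25 (camera adjusted p = 0.086). Of the BMP list 3 of 8 fell (3 alone). Its median was -0.90 (camera adjusted p = 0.284). Of the LXR list 1 of 10 rose and 4 fell (1 and 4 alone). Its median was -0.60 (camera adjusted p = 0.227). Of the cholesterol list 11 of 23 rose and 1 fell (11 and 1 alone). Its median was 0.65 (camera adjusted p = 0.159). Of the border macrophage list 4 of 14 rose and 6 fell (4 and 7 alone). Its median was -0.74 (camera adjusted p = 0.0586). Of the inflammatory list 8 of 17 rose and 4 fell (9 and 4 alone). Its median was 1.59 (camera adjusted p = 0.31).

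Among cell type lists, the pericyte and fibroblast genes fell. Of that list 7 of 7 fell (7 adjusted over the list alone). Its median was -7.22 (camera p = 0.000557, adjusted p = 0.279 with an estimated correlation), and -6.77 with the genes at 0 counts at their bounds. Of the neuron list 6 of 8 rose and 1 fell (6 and 1 alone). Its median was 5.36 (camera p = 0.0238, estimated-correlation p = 0.465), and 4.99 with the gene at 0 counts at its bound. Of the oligodendrocyte list 5 of 7 rose and 1 fell (6 and 1 alone). Its median was 3.94 (camera adjusted p = 0.364), and 3.79 with the gene at 0 counts at its bound. Of the progenitor list 1 of 3 fell (1 alone). Its median was -0.25 (camera adjusted p = 0.0788). Of the astrocyte list 3 of 12 rose and 6 fell (3 and 6 alone). Its median was -0.58 (camera adjusted p = 0.679). Of the endothelial list 2 of 5 rose and 2 fell (2 and 2 alone). Its median was -0.29 (camera adjusted p = 0.632). Of the monocyte and neutrophil list 5 of 8 rose and 2 fell (5 and 2 alone). Its median was 5.61 (camera adjusted p = 0.397). Its level, as mean log2(CPM + 1), was 7.34 in replicate 5 and 3.62 to 3.72 in the others, and 5 rose and 2 fell without replicate 5, with a median of 2.86. Of the T and NK cell list 1 of 3 rose (0 alone). Its median was 0.56 (camera adjusted p = 0.729). Of the B cell list 4 of 4 rose (4 alone). Its median was 4.44 (camera adjusted p = 0.0788). Of the erythroid list 1 of 2 rose and 0 fell (1 and 1 alone). Mitochondrial genes took 3.4 ± 1.01 percent of counts ex vivo and 0.782 ± 0.168 percent in culture. The ex vivo animals were others than the cultured ones, so that culture and animals changed together and no pairs could be formed.

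The genes of the ex vivo comparison with an absolute log2 fold change of at least 1 gave a set of 3136 genes high ex vivo and a set of 2853 genes low ex vivo, chosen on these data, which were then followed in comparisons that share no libraries with it. At 18 days of washout 750 of 2676 genes of the high set rose and 195 fell (median 0.25, camera p = 6.28e-06, adjusted p = 0.282 with an estimated correlation), and of 2836 genes of the low set 336 rose and 1131 fell (median -0.27, camera p = 4.18e-09, estimated-correlation p = 0.148). At 4 days 415 rose and 193 fell of the high set (median 0.11, camera p = 0.00491, estimated-correlation p = 0.324), and 287 rose and 551 fell of the low set (median -0.16, camera p = 0.00441, estimated-correlation p = 0.312). In spheres against serum 277 of 2443 genes of the high set rose and 32 fell (median 0.25, camera p = 8.71e-06, estimated-correlation p = 0.282), and of 2725 genes of the low set 86 rose and 199 fell (median -0.26, camera p = 9.86e-07, estimated-correlation p = 0.153). In spheres 14 of 14 oligodendrocyte, 9 of 13 astrocyte and 4 of 5 neuron genes rose too, and ex vivo these lists had medians of 3.94, -0.58 and 5.36. With IL-34 plus TGF-b against M-CSF plus TGF-b 61 of 2693 genes of the high set rose and 16 fell (median 0.08, camera p = 0.00877, estimated-correlation p = 0.312), and 45 rose and 63 fell of the low set (median -0.07, camera p = 0.00534, estimated-correlation p = 0.282). After washout in the sphere experiment 94 rose and 92 fell of the high set (median 0.07, camera p = 0.162, estimated-correlation p = 0.619), and 128 rose and 276 fell of the low set (median -0.13, camera p = 0.0144, estimated-correlation p = 0.312). At 22 against 18 days 0 genes were called and the sets went the other way, the high set with median -0.05, camera p = 0.0027, estimated-correlation p = 0.312, and the low set with median 0.04, camera p = 0.0143, estimated-correlation p = 0.312. With TGF-b on IL-34, where 0 were called too, the high set had median -0.05, camera p = 0.0323, estimated-correlation p = 0.312, and the low set median 0.01, camera p = 0.137, estimated-correlation p = 0.396.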

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

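The tests on the homeostatic genes of the spheres, with the fibroblast covariate and on the matrix genes outside the fibroblast-made ones were chosen after the result was seen; the other tests of this part were planned. Chance sets a library apart in about 5 percent of groups of 4; of 365 groups looked at, 28 held such a library.

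The homeostatic list was higher in spheres than after 11 days of washout (median 0.73; adjusted p = 0.221 with an estimated correlation, 0.0278 blocked), although its called members, BIN1 and MERTK, are also expressed by oligodendrocytes or astrocytes. Neural RNA as the whole cause is argued against by the 7 microglia-restricted anchors P2RY12, P2RY13, TMEM119, CX3CR1, SALL1, CSF1R and GPR34, whose median log2 fold change was 1.13 and lay at 1.41, 1.93, 1.09 and 0.55 in the 4 animals. Scaling stays open: the list median was 0.74 with median-of-ratios factors, but these kept 898 of the 902 calls and so changed too little to test it. Microglia brought in with the neural cells stay open: 2 T and NK cell genes, NKG7 and CD2, rose in spheres. Such cells cannot be told apart from an effect of co-culture, because added cells and medium changed together. The rise over washout may thus be a change of the cells or of their source. Against serum, P2RY12 (220 against 377 CPM) and CSF1R (1790 against 2470) averaged lower, the other anchors higher.

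The matrix list was lower with IL-34 plus TGF-b than with M-CSF plus TGF-b (median -0.59, 6 genes lower; adjusted p = 0.0888 with an estimated correlation), together with the pericyte and fibroblast list (adjusted p = 0.0781 likewise). With the level of that list as a covariate the median was 0.29, with 0 genes lower and 1 higher (camera adjusted p = 0.886). The median SE went from 0.4 to 0.44. Fewer fibroblasts or pericytes with IL-34 stay open: matrix genes of any cell could follow this covariate. The covariate was tied to the cytokine (r = -0.92 over the 8 libraries), yet the MHC class II median only went from 1.33 to 1.07 and the 303 called genes had a median ratio of log2 fold changes with and without it of 0.97, with SEs 1.54 times as large. A change in the microglia stays open too: 9 matrix genes outside the fibroblast-made ones had a median of -0.44 (median absolute deviation 1.09), 1 called lower.

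No gene was called by edgeR or DESeq2 between 22 days without serum and 18 days of washout after 4 days of serum. At an unadjusted p below 0.05 edgeR had 261, 1126 blocked and up to 961 without single libraries. Low precision is argued against for most genes: 77.6 percent of tested genes had a 95 percent interval within a 2-fold change, in the fit without the animal. Too few replicates are argued against by simulated counts, where 81.5 percent of 4-fold changes were called. Early serum may have left few lasting 4-fold differences, while smaller ones stay open. CX3CR1 was lower at 22 days in each animal (53.35 against 80.46 CPM in replicate 6, 0.521 against 17.2 in replicate 8).

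Over all splits, pairs ignored, only 1 of 35, the real one, gave as many genes in several comparisons. These were IL-34 against M-CSF (581; highest other split 0), 4 days (3374; 50), 11 days (4411; 68), 18 days (5207; 652) and 22 days without serum (5686; 552), 18 against 4 days (1544; 0), 11 days of washout in the sphere experiment (1095; 0), spheres against serum (1310; 0) and against washout (902; 0), and ex vivo against culture (8701; 0). Except ex vivo, libraries are paired by animal, and the 8 splits that part all pairs are too few for a share under 5 percent; their highest other was 110 at 18 days, 10 at 22 days and 0 for the rest. For IL-34 plus TGF-b against M-CSF plus TGF-b 2 of 35 splits did, since a split by animals, which parts no pair, called 514 genes against 303. Between 22 and 18 days a split by animals called 533 genes against the real 0 (35 of 35): both point to the animals as a structure of the samples. Where 0 genes were called every split gives as many, so the splits say nothing on chance: TGF-b on M-CSF (35 of 35 splits, highest other 1), TGF-b on IL-34 (35 of 35, 0), the difference of the washout effects (35 of 35, 0) and the difference of the TGF-b effects (100 of 100 drawn splits, 17).

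The gap between the medians of the ex vivo-high and ex vivo-low sets was tested by the same splits. The real split was the largest at 11 days (0.46; highest other 0.42; 1 of 35) and 18 days of washout (0.52; 0.51; 1 of 35), both by a narrow margin. It was not at 4 days (0.27; 0.27; 2 of 35), at 22 days (0.45; 0.46; 2), at 18 against 4 days (0.28; 0.32; 2), in spheres against washout (0.3; 0.32; 2) or serum (0.51; 0.66; 5), after washout in the sphere experiment (0.2; 0.55; 14), with IL-34 in the presence of TGF-b (0.14; 0.28; 8), with TGF-b on IL-34 (-0.06; 0.18; 17) and at 22 against 18 days (-0.09; 0.32; 19). Among the 8 splits that part all pairs, too few for a share under 5 percent, the real one was the largest for each of these except spheres against serum and washout in the sphere experiment, where 2 were as large, and TGF-b on IL-34, where 3 were.

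Effects of whole lists that differed between groups were as follows, each by camera on the difference itself. After each median difference, parentheses give camera's adjusted p and the one with an estimated correlation, with which each call was lost. The effect of TGF-b was higher on IL-34 than on M-CSF for the interferon list, 1.18 (1.61e-12 and 0.458), the cell cycle list, 0.18 (0.0364 and 0.907), and the glycolysis list, 0.19 (0.046 and 0.765). It was lower for the fibroblast list, -1.54 (1.67e-07 and 0.205), the astrocyte list, -0.65 (0.0364 and 0.765), and the matrix list, -0.31 (0.000124 and 0.458). It was also lower for the TGF-beta list, -0.26 (0.00476 and 0.458), the homeostatic list, -0.19 (0.046 and 0.765), and the lysosome list, -0.11 (0.046 and 0.859). The effect of 11 days of washout was higher in the sphere than in the washout experiment for cholesterol synthesis, 0.78 (3.19e-10 and 0.171). It was lower for the fibroblast, -1.60 (0.00162 and 0.343), TGF-beta, -1.12 (1.39e-05 and 0.122), astrocyte, -1.06 (0.00931 and 0.282), and cell cycle lists, -0.77 (0.00178 and 0.579). Lower too were the border macrophage, -0.73 (0.000518 and 0.122), matrix, -0.72 (0.0163 and 0.391), endothelial, -0.61 (0.00878 and 0.122), and complement lists, -0.56 (0.00162 and 0.122). So were the homeostatic, -0.43 (0.0067 and 0.336), MHC class II, -0.40 (0.0235 and 0.391), and lysosome lists, -0.36 (0.00184 and 0.343).

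Single libraries stood apart from the other 3 of their group in the values that follow, with the range of the others in parentheses; list levels are mean log2(CPM + 1). With M-CSF these were the LXR list in replicate 4 at 5.57 (5.28 to 5.33) and the immediate early list in replicate 2 at 5.05 (5.29 to 5.31). With IL-34 these were the inflammatory list at 4.31 (4.44 to 4.47) and the T and NK cell list at 4.96 (4.01 to 4.1) in replicate 4, the border macrophage list in replicate 2 at 6.09 (6.41 to 6.46) and the glycolysis list in replicate 3 at 7.13 (7.34 to 7.38). With M-CSF plus TGF-b, the 10 most abundant genes took 18.8 percent of counts (14.4 to 15) and 16277 genes were detected (15793 to 15816) in replicate 1, and the fibroblast list was at 3.58 (4.15 to 4.17) in replicate 2. With IL-34 plus TGF-b, 15516 genes were detected (15844 to 15857) and the border list was at 6.13 (6.58 to 6.64) in replicate 3, the cell cycle list at 5.86 (7.12 to 7.21) in replicate 1 and the immediate early list at 4.9 (5.17 to 5.22) in replicate 2. Ex vivo, replicate 5 held the monocyte and neutrophil list at 7.34 (3.62 to 3.72) and the border list at 6.13 (5.67 to 5.71).

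In the washout experiment SPP1 took 6.32 percent of counts (7.25 to 7.39) at 4 days and 4.46 percent (5.54 to 5.76) at 11 days in replicate 8. Replicate 8 also held the interferon list at 5.4 (4.96 to 5) at 11 days and the inflammatory list at 4.66 (5.08 to 5.16) at 18 days. Replicate 6 held the BMP list at 4.33 (4.46 to 4.48) and the T and NK cell list at 2.58 (2.37 to 2.4) at 4 days, the oligodendrocyte list at 3.77 (1.89 to 1.97) at 11 days and the endothelial list at 4.66 (4.36 to 4.38) at 22 days, and replicate 5 the interferon list at 4.18 (4.78 to 4.86) at 18 days. In the sphere experiment replicate 9 held the interferon list at 6.77 (4.38 to 4.67) and the disease-associated list at 9.66 (9.71 to 9.71) after washout and the astrocyte list at 2.24 (2.76 to 2.84) in serum, and replicate 11 the endothelial list at 3.51 (3.79 to 3.82) in spheres.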

How the results depend on the processing

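The fits without animal 9 and with the fibroblast covariate were chosen after the data were seen; the other settings were planned. The first kept 406 of 1095, 899 of 1310 and 620 of 902 calls of the sphere experiment, the second 549 of the 581 and 53 of the 303 calls of IL-34 without and with TGF-b. No called gene changed sign with DESeq2, median-of-ratios scaling, no filter, the block or only the 2 groups, and median-of-ratios scaling and dropping the low-count filter left each total of both directions within 1.5 times; without the filter the 727 genes higher at 18 than at 4 days were 479. The totals of 8701 genes ex vivo and of 4411, 5207 and 5686 genes at 11, 18 and 22 days without serum stayed within 1.5 times in every setting, and 0 genes were called at 22 against 18 days in each. With only the 2 groups, the 2607 genes higher at 18 days were 1672 and the 1671 lower at 4 days 1095.

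With the animal as a replicate block the numbers of called genes were 2542 for IL-34 against M-CSF, 27 and 9 for TGF-b added to M-CSF and to IL-34, 1360 for IL-34 against M-CSF in the presence of TGF-b, 5421 for 4 days and 3390 for 18 against 4 days of washout, 1726 for washout in the sphere experiment and 2018 for spheres against serum. The 211 genes lower in spheres than after washout were 369 with the block, 440 with DESeq2 and 335 with only the 2 groups. Pairing by animal moved no other total of called genes by more than 1.5 times and changed no other call named in the text. With DESeq2 the totals were 1084 for IL-34, 11 and 10 for TGF-b on M-CSF and IL-34, 627 for IL-34 with TGF-b, 1806 for washout in the sphere experiment, 2146 and 1677 for spheres against serum and washout, and 45 for the difference of the washout effects. With only the 2 groups compared, 183 genes were called for IL-34 with TGF-b and 612 for washout in the sphere experiment, where fewer libraries informed the spread. With the fibroblast covariate 91 genes were called for IL-34 with TGF-b, and without animal 9 457 for washout in the sphere experiment. The cause was not tested for the other changes. Ex vivo, the median log2 fold change of all genes was 0.22 with DESeq2, which tested more genes, against -0.01.

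Leaving out each library in turn gave 362 to 656 genes for IL-34 against M-CSF, 0 to 2 for TGF-b on M-CSF, 198 to 250 for IL-34 with TGF-b, 0 to 1 for the difference of the TGF-b effects, 974 to 1552 for 18 against 4 days, 654 to 1340 for washout in the sphere experiment and 0 to 2 for the difference of the washout effects. Of 16485 such refits of named genes 15767 kept their side of the threshold, 627 lost the call and 91 gained it.

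With an estimated correlation 138 of 385 list tests lost their call and 247 kept their side, and 11 calls were left in all; of 22 tests of the ex vivo sets 20 lost it, 2 kept their side and 0 calls were left. The block kept the side of 343 of 360 list tests (15 gained, 2 lost) and of all 22 set tests, and median-of-ratios scaling that of 380 of 385 (3 gained, 2 lost). Of the 20 set calls, sets with an absolute log2 fold change of at least 2 lost 3, and sets without cell type, cell cycle and immediate early genes 0. Of 1846 results of named genes 1730 kept their side with DESeq2 (108 gained, 8 lost), 1845 with median-of-ratios scaling (1 lost) and 1817 without the filter (12 gained, 17 lost). With the block 1534 of 1729 kept theirs (191 gained, 4 lost), with only the 2 groups 1338 of 1436 (30 gained, 68 lost), with the covariate 411 of 449 (7 gained, 31 lost) and without animal 9 395 of 472 (8 gained, 69 lost). At these depths and spreads 37.9 percent of simulated 4-fold differences between washout effects and 83.1 percent of those between TGF-b effects were called.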

Other observations

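No test was run for the values of this part, which were looked up after the other results were seen. APOE was low throughout the sphere experiment. It averaged 37 ± 30.7 CPM in serum, 126 ± 42.3 CPM after 11 days of washout and 207 ± 122 CPM in spheres (SD, n = 4), against 1590 ± 677 CPM in serum and 10500 ± 368 CPM after 11 days of washout in the washout experiment and 2830 ± 1170 CPM ex vivo. SPP1 went the other way, at 189000 ± 29000 CPM in the sphere experiment's serum group and 58400 ± 11900 CPM in that of the washout experiment. TREM2, a lipid receptor of microglia, stood at 310 ± 128 and 104 ± 59.5 CPM in the same groups. Kit, animals, age, sex and gene naming changed together between these experiments, so no source of the gap can be named.

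The summed CPM of erythroid genes was 76.6 ± 44.2 ex vivo (22.6 to 129), and the culture groups had means of 15.6 to 34.3 CPM, with single libraries of up to 45.8.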
